A study of Mus musculus with 43 samples.

How the data were processed

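RNA sequencing values of 43 libraries in 10 groups were taken from the deposited tables, which cover oocytes, zygotes and 2-cell embryos from females on normal diet (ND) or high-fat diet (HFD) and 2-cell embryos after siRNA microinjection. The deposited files hold FPKM, made by the authors by scaling reads to the exon length of each gene and to the reads of each library. No header names the unit, so it was read from the values. For genes with 1 annotated transcript, 98.4 to 99.1% of low values (up to 20 reads) were whole multiples of 1 step per library, within 0.1 read, and 94.7 to 97.0% over all genes. The columns summed to 315121 to 390269. The step, from genes with at least 300 bases of exon, gave the depth of each library, 9.01 to 21.37 M reads (M is mega), and the reads behind each value. The genome build GRCm38 and the demultiplexer bcl2fastq are named in the submitters' processing notes. The aligner, the counting tool and the filters are not given in the sources used here. Reads carry no molecular identifiers, so depth limits counting error only and says nothing of the number of starting molecules.

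Of 39081 genes listed in at least 1 file, 38992 had an exon length in GENCODE M21, and 94.1% of these had the same position there. ND GV replicate 4 was identical to ND GV replicate 1 at all 27648 genes listed and was left out, so 42 libraries entered the tests. The siAbcd3 replicate 1 file ends early, with 33460 genes against 34886 in the other 8 knockdown files, and for its 1426 missing genes limma fitted the other libraries, while camera, voom and the correlation of the knockdowns left them out. For 10 libraries a second copy existed in another file, and all 10 copies were identical. Genes not listed in a table were taken as 0. Knockdown libraries share 1 table, as do ND GV and ND zygote libraries, the MII libraries and the 2-cell libraries of both diets. HFD GV libraries have a table of their own. The files name no other batch, but the sample records of the HFD MII libraries are numbered apart from those of all other libraries, so they may have been registered at another time.

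Choices of groups, comparisons, tests, gene lists and alternatives were made before the data were examined. They foresaw counts and named a fallback for normalized values, which was used because the files hold FPKM. Genes with a mean of at least 1 FPKM over the groups fitted were tested with limma 3.58.1 (eBayes with trend and robust) in R 4.3.3 on log2(FPKM + 1), with data.table (version 1.17.8), and p values were adjusted by Benjamini-Hochberg (BH), with an adjusted p under 0.05 as a call. The pseudocount of 1 makes fold changes of genes near 1 FPKM smaller than their ratios. The 3 knockdown groups were fitted together, the 4 ND stages together, and each diet comparison on its own. The difference between the diet effects at the 2-cell stage and at GV was tested as an interaction in 1 fit of the 4 groups.

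In the knockdown groups each library resembled the library with the same number in the other groups more than those with other numbers. After subtracting group means, Pearson r across genes of libraries with the same number was 0.23 to 0.424 for siAcox1 and control, 0.213 to 0.419 for siAbcd3 and control and 0.376 to 0.679 for the knockdowns, in each case the highest for that library. A fit with the number as a pair is therefore given beside the unpaired fit. For the other groups the number was not shown to link libraries.

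There were 27 gene lists with 960 entries on peroxisomes, ether lipids, lipid and methyl metabolism, chromatin, zygotic activation, pluripotency, imprinting, maternal RNA, ribosomes, the respiratory chain, stress responses, and markers of cumulus, sperm and blood cells. They were tested with camera (preset correlation 0.01), BH over the lists of a comparison, with fry and with camera using a correlation estimated from the data beside it. Members past the gene test were counted over all genes and adjusted over the list alone. Activation and decay lists hold genes called with an absolute log2 fold change of at least 2 between ND zygotes and 2-cell embryos. Quality measures (depth, genes at 1 FPKM or more, share of the 10 top genes, of 19 mitochondrial DNA genes and of ribosomal protein genes) were compared by exact permutation tests, 45 in all, 2-sided, BH adjusted. Between 3 and 3 libraries such a test gives at least 0.1. Correlations of fold changes, relabelled libraries and tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

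The rule for named genes took Acox1 and Abcd3 always. It added the 8 largest changes in each direction among genes with an adjusted p under 0.05, a mean log2(FPKM + 1) of at least 4 (in place of log2 counts per scaled library, which the files do not hold), no overlap between the groups and a symbol that is no Gm number, Rik name, pseudogene or bare Ensembl identifier, while clone-based names such as AC239878.1 were kept. From each list that passed camera, and from 5 lists on the subject of the series in the knockdown and 2-cell diet comparisons, it took up to 4 members with the smallest adjusted p. The same rule was applied to the paired fits. A gene whose symbol the files hold as a date is not named, and of long lists of named members a part is printed.

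The method was tested on simulated data, with reads drawn from a negative binomial at the depth and spread of these libraries and 200 genes changed in each comparison. Of genes raised 4-fold, 44 to 48% were recovered in the knockdown comparisons without pairs and 86 to 98% in the other comparisons. Of genes raised 2-fold, 0 to 8% were recovered in the knockdown and 36.7 to 88% in the other comparisons, and of genes raised 1.5-fold 0% and 2 to 50%. False calls numbered 1 to 11 per comparison. Genes were drawn independently of each other, so these numbers do not cover false calls from deviations that many genes of a library share.

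Alternatives were a pseudocount of 0.1, no filter, a mean of at least 100 recovered reads, median-of-ratios scaling, the replicate number as a block, only the groups compared or all diet libraries in a fit, both copies of the identical library, ND and control embryos together as the normal group, an absolute log2 fold change of at least 1, other list tests, other activation lists and leaving out each library. Limma-voom on recovered reads, genes listed in all files, leaving out 3 HFD MII or 2 HFD 2-cell libraries, lists with control embryos in the normal group, exchanges within pairs for the correlation with siAcox1 and the alternatives of the paired fit were added after seeing the data. Other splits of the same libraries, at most 100 per comparison, were fitted in the same way.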

Results

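Mouse oocytes and early embryos were profiled by RNA sequencing after Smart-Seq2 amplification, which copies polyadenylated RNA of very small samples from an oligo-dT primer. The diet series held fully grown oocytes arrested in prophase (germinal vesicle, GV), mature oocytes arrested at metaphase II (MII) and 2-cell embryos from females on a normal diet (ND) or a high-fat diet (HFD), and ND zygotes. It had 4 ND GV, 4 HFD GV, 6 ND MII, 6 HFD MII, 3 ND zygote, 3 ND 2-cell and 8 HFD 2-cell libraries. The knockdown series held 2-cell embryos that developed from zygotes microinjected with small interfering RNA (siRNA) against Acox1 (siAcox1) or Abcd3 (siAbcd3), and control embryos, with 3 libraries each. Acox1 encodes the oxidase that starts peroxisomal beta-oxidation, and Abcd3 encodes a peroxisomal membrane transporter of fatty acids. ND GV replicate 4, identical to replicate 1, was left out. Females and pools are not named, so n counts libraries, which tests take as independent. Depth, recovered from the smallest steps of the values, was 9.01 to 15.2 M reads in control, 16.2 to 16.7 in siAcox1 and 13.2 to 16.5 in siAbcd3 embryos. It was 15.2 to 15.9 M reads in ND GV, 15.8 to 20.2 in HFD GV, 15.8 to 21.4 in ND MII, 15.8 to 20.7 in HFD MII and 16.7 to 18.4 in ND zygote libraries. ND 2-cell libraries had 12.45 to 16.0 M reads and HFD 2-cell libraries 11.5 to 15.7.

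Values are in FPKM (fragments per kilobase of exon, scaled to the reads of each library), as mean ± SD over the libraries of a group, and changes are log2 fold changes of FPKM + 1, with their SE where given. Adjusted p values of genes are from limma with Benjamini-Hochberg (BH) correction, and those of gene lists from camera with BH correction over the lists of a comparison. FPKM is a share of the RNA copied in a library, so more or less RNA here means a higher or lower share, not an amount per oocyte or embryo. Because the primer copies polyadenylated RNA, a change of the poly(A) tails cannot be told apart from a change of the RNA itself. Coordinates are on GRCm38.

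The first knockdown comparison addressed which transcripts of 2-cell embryos depend on Acox1. Acox1 (ENSMUSG00000020777, chromosome 11, 116171888 to 116199045) stood at 18.9 ± 5.71 FPKM in siAcox1 (n = 3) and at 33.5 ± 3.34 FPKM in control embryos (n = 3). Libraries with the same replicate number resembled each other, and with the number as a pair Acox1 fell, with a log2 fold change of -0.83 ± 0.23. It also lay lower in siAbcd3 embryos, with a paired log2 fold change of -0.47, but did not pass there (limma adjusted p 0.34). In the paired siAcox1 fit 49 of 72 genes for making ribosomes fell and 32 of 58 oocyte genes rose. Both lists passed camera, but had adjusted p = 0.919 with an estimated correlation. Grwd1, a chaperone of ribosomal proteins, fell by 2.23 on the log2 scale, and H1foo, the linker histone of oocytes, rose by 2.24. No gene passed without pairs.

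Without pairs, limma with BH correction called 0 of 12545 genes, with 2816 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.131, and limma-voom called 0 genes with 2702. With pairs, limma called 2577 genes, 1064 higher and 1513 lower, and 1521 of them changed at least 2-fold (582 higher, 939 lower). For Acox1 the limma adjusted p was 0.156 without and 0.0414 with pairs. The 8 largest rises named by rule in the paired fit were H1foo, Ifitm6, Ninj2, Miox, Immp1l, Tmem230, AC239878.1 and Sec22a. H1foo (ENSMUSG00000042279, chromosome 6, 115944938 to 115950236) was at 346 ± 197 FPKM against 66.0 ± 26.7 in controls, and Immp1l, a subunit of the mitochondrial inner membrane peptidase, was at 1060 ± 449 against 285 ± 137. The 8 largest falls were Pgp, Grwd1, Zscan5b, Exoc3l2, Rars, Rrs1, Trmt10c and Mrpl43. Grwd1 (ENSMUSG00000053801, chromosome 7, 45825223 to 45830944) was at 28.2 ± 11.1 against 139 ± 68.0 FPKM, and Pgp, a phosphatase of 2-phosphoglycolate, at 9.92 ± 4.65 against 49.2 ± 4.37. Rars charges arginine tRNA, Rrs1 assembles the large ribosomal subunit, Trmt10c methylates mitochondrial tRNA and Mrpl43 is a mitochondrial ribosomal protein. By limma, adjusted p of these 16 genes ran from 0.0128 to 0.0278 with pairs and from 0.131 to 0.176 without. The paired count was 0 without pair 1, 0 without pair 2 and 1253 without pair 3, and it was 0 when only the 2 groups entered the fit or when low values were not filtered.

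In the paired fit 49 of 72 ribosome biogenesis genes fell and 0 rose (60 fell adjusted over the list alone), with a median log2 fold change of -1.08. The camera adjusted p was 6.41e-17, the adjusted p = 0.919 with an estimated correlation, and the fry adjusted p 0.0194. Beside Grwd1, Imp4 and Ddx56, which act in ribosomal RNA maturation, fell by 1.25 and 1.60, and Ebna1bp2, a nucleolar factor, fell by 1.66. Of 58 maternal-effect and oocyte genes, 32 rose and 1 fell (37 and 1 adjusted over the list alone), with a median of 0.94. The camera adjusted p was 3.21e-13, the adjusted p = 0.919 with an estimated correlation, and the fry adjusted p 0.0194. Oosp1, an oocyte-secreted protein, rose by 1.82 (2200 ± 248 against 662 ± 265 FPKM), Oog4 by 1.74, Zar1, a maternal RNA-binding protein, by 1.58 and Gdf9, an oocyte growth factor, by 1.42. Of 77 cytosolic ribosomal protein genes, 6 fell, among them Rpl29 (-2.0), Rpl8 (-0.98) and Rpl6 (-1.11), and 1 fell adjusted over the list alone, while Rpl21 (-0.99, adjusted p 0.0987) did not pass. This list had a median of -0.57, a camera adjusted p of 0.000176, adjusted p = 0.919 with an estimated correlation, and a fry adjusted p of 0.376. Without pairs 30 ribosome biogenesis genes fell and 16 oocyte genes rose adjusted over the list alone. The unpaired camera adjusted p was 8.42e-15 for ribosome biogenesis, 2.22e-11 for oocyte genes and 0.000409 for ribosomal proteins, with adjusted p = 0.96 with an estimated correlation for each. siAcox1 replicate 2 held 0.67% of its FPKM in ribosomal protein genes, and the group 1.32 ± 0.565% against 1.99 ± 0.437% in controls. The 10 top genes took 15.7 to 19% of FPKM in siAcox1 against 13.2 to 13.9% in control libraries, and mitochondrial DNA genes 11.7 to 13.6% against 9.94 to 11.6%. Both had an exact permutation p of 0.1 (adjusted 0.15), the smallest that 3 against 3 libraries can give.

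**Figure D1:**
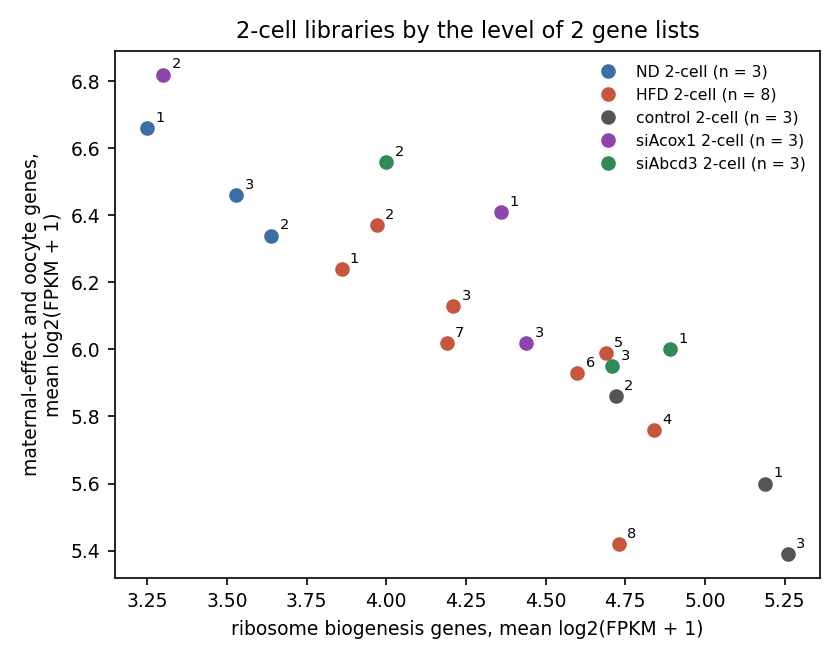
Mean log2(FPKM + 1) of the ribosome biogenesis list (x axis) and of the maternal-effect and oocyte list (y axis) in each of the 20 libraries from 2-cell embryos, 1 point per library, coloured by group. siAcox1 libraries lie at 3.30 to 4.44 on the x axis and control libraries at 4.72 to 5.26, and ND libraries at 3.25 to 3.64 and HFD libraries at 3.86 to 4.84.

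Of the lists on the subject of the series, none of the following 5 passed camera in the paired siAcox1 fit. Of 14 genes of peroxisomal beta-oxidation, Acox1 was the 1 that fell (camera adjusted p 0.82), while Pecr (0.70, adjusted p 0.0653 by limma), Lonp2 (0.60, 0.102) and Decr2 (-0.90, 0.0644) did not pass. Of 30 genes of methionine and one-carbon metabolism, 1 rose and 7 fell (camera adjusted p 0.216), including Shmt1 (-1.44), a folate enzyme, Srm (-1.03), the spermidine synthase, Enoph1 (-0.90), which acts in methionine salvage, and Dhfr (-0.70). Of 30 phospholipid synthesis genes, 5 rose and 3 fell (0.954), with Lpin2 (1.12) and Lpcat2 (1.57) higher and Ptdss2 (-1.32), a phosphatidylserine synthase, and Cdipt (-0.97), the phosphatidylinositol synthase, lower. This list had a median of -0.19 while camera ranked it up. Of 37 histone methyltransferase genes, 2 rose and 3 fell (0.383), with Ezh2 (0.82) higher and Ash2l (-0.87) and Smyd5 (-1.51) lower, while Wdr5 (-0.60, adjusted p 0.0539 by limma) did not pass. Of 51 genes of the minor wave of zygotic genome activation (ZGA), 2 rose and 7 fell (0.82), with Pramel7 (-1.46), Tdpoz2 (-1.38), Dppa2 (-1.05) and Pramel6 (-1.03) lower. Their median was 0.05 and their mean -0.05. Adjusted over the list alone, 0 peroxisomal genes passed, 1 methionine gene rose and 8 fell, 5 phospholipid genes rose and 4 fell, 2 methyltransferases rose and 8 fell, and 2 ZGA genes rose and 7 fell. Fry, which tests a list without regard to other genes, passed the methionine list downward (fry adjusted p 0.0239). It also passed peroxisome biogenesis (0 rose and 2 fell of 12, 1 and 2 adjusted over the list alone, camera adjusted p 0.643, fry adjusted p 0.038) and mitochondrial beta-oxidation (0 rose and 4 fell of 20, also adjusted over the list alone, camera adjusted p 0.383, fry adjusted p 0.0194), both downward.

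Genes at least 4-fold higher in ND 2-cell embryos than in ND zygotes, the activation list, and genes at least 4-fold lower, the decay list, come from other libraries than the knockdowns. In the paired siAcox1 fit 250 of 1065 activation genes fell and 25 rose, with a median of -0.61. The camera adjusted p was 2.5e-09, the adjusted p = 0.31 with an estimated correlation, and the fry adjusted p 0.0731. Of 339 decay genes 51 rose and 19 fell, with a median of 0.35, a camera adjusted p of 2.16e-06, adjusted p = 0.148 with an estimated correlation, and a fry adjusted p of 0.0282. Without pairs the camera adjusted p was 1.9e-09 for activation and 1.24e-06 for decay genes, with adjusted p = 0.264 and adjusted p = 0.0781 with an estimated correlation.

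The second comparison of this series took embryos injected with siAbcd3. Abcd3 (ENSMUSG00000028127, chromosome 3, 121758774 to 121815302) was at 0.516 ± 0.153 FPKM in siAbcd3 (n = 3) and 0.496 ± 0.161 FPKM in control embryos (n = 3), under the filter of 1 FPKM, so the target was not tested and a lower level of it was not seen. In siAcox1 embryos it was at 1.01 ± 0.164 FPKM. As lists, oocyte genes lay higher and ribosome biogenesis genes lower than in controls, with medians of 0.63 and -0.51, but no single gene passed and both lists had adjusted p = 0.843 with an estimated correlation. Acox1 was at 23.9 ± 0.559 FPKM in siAbcd3 embryos against 33.5 ± 3.34 in controls, with a limma adjusted p of 0.737. Limma called 0 genes with 804 at an unadjusted p under 0.05, and voom 0 with 655. With pairs limma called 0 genes with 2170, and voom 0 with 2115. The 10 top genes took 15.4 to 17.8% of FPKM in siAbcd3 against 13.2 to 13.9% in control libraries (exact permutation p 0.1, adjusted 0.15).

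Oosp1 was at 1680 ± 145 FPKM in siAbcd3 against 662 ± 265 in controls, H1foo at 284 ± 190 against 66.0 ± 26.7, Npm2, the oocyte nucleoplasmin, at 398 ± 94.5 against 169 ± 41.7, and Gdf9 at 101 ± 33.7 against 50.5 ± 11.4. Grwd1 was at 52.2 ± 17.4 FPKM against 139 ± 68.0, Ddx56 at 15.2 ± 5.01 against 34.9 ± 14.5 and Imp4 at 26.7 ± 0.636 against 41.6 ± 3.52, and by limma all 7 had an adjusted p of 0.737. The camera adjusted p was 3.21e-10 for oocyte genes and 6.13e-10 for ribosome biogenesis, and with an estimated correlation each had adjusted p = 0.843. Unpaired, 0 members of either list passed over all genes or adjusted over the list alone. With pairs both lists had a camera adjusted p of 6.77e-13 and adjusted p = 0.792 with an estimated correlation, and 18 oocyte genes rose and 12 ribosome biogenesis genes fell adjusted over the list alone. The 5 lists on the subject of the series did not pass camera, with adjusted p of 0.512 for peroxisomal beta-oxidation, 0.338 for methionine metabolism, 0.862 for phospholipid synthesis, 0.338 for histone methyltransferases and 0.666 for minor ZGA. The activation list had a median of -0.20 and a camera adjusted p of 0.00787, with adjusted p = 0.606 with an estimated correlation. The decay list had a median of 0.14 and a camera adjusted p of 0.000579, with adjusted p = 0.183 with an estimated correlation.

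The direct comparison of siAcox1 with siAbcd3 embryos asked whether embryos of the 2 siRNA groups differ. Ribosome biogenesis genes lay lower in siAcox1 than in siAbcd3 embryos, with a median of -0.52 over 72 genes, as did ribosomal protein genes (-0.44 over 77), and oocyte genes lay higher (0.28 over 58), each with adjusted p = 0.951 with an estimated correlation. Ebna1bp2 was at 49.5 ± 18.2 FPKM in siAcox1 against 105 ± 28.7 in siAbcd3, Imp4 at 17 ± 2.39 against 26.7 ± 0.636 and Zar1 at 7.39 ± 0.781 against 4.02 ± 1.71, each with a limma adjusted p of 0.988. Acox1 was at 18.9 ± 5.71 FPKM in siAcox1 and 23.9 ± 0.559 in siAbcd3 embryos and was not called. The camera adjusted p was 7.57e-12 for ribosome biogenesis, 1.7e-06 for ribosomal proteins and 2.04e-05 for oocyte genes. Activation genes had a median of -0.43 and a camera adjusted p of 2.28e-14, with adjusted p = 0.168 with an estimated correlation. Limma called 0 genes with 291 at an unadjusted p under 0.05 and voom 0 with 281, and with pairs limma called 0 with 1239 and voom 0 with 1371. Across 12049 genes the fold changes of siAcox1 and siAbcd3 against control had a Pearson r of 0.841 and a covariance of 0.272. In 1000 simulations of unchanged groups against the same controls the mean r was 0.45 and its 95th percentile 0.92, and the mean covariance was 0.096 and its 95th percentile 0.304. A covariance as large arose in 65 simulations, and in 13 when the simulation kept the pairs, and the 3 controls cannot be split between the comparisons.

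**Figure D2:**
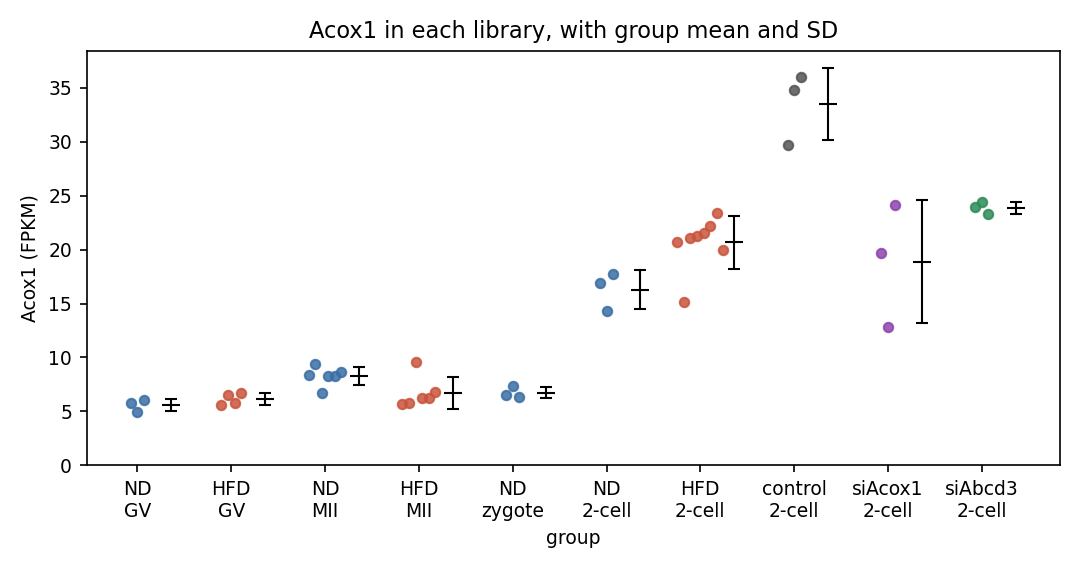
FPKM of Acox1 in each library (points), with the mean and SD of each of the 10 groups (bars and lines). siAcox1 embryos had 18.9 ± 5.71 FPKM against 33.5 ± 3.34 in controls, and ND 2-cell embryos 16.3 ± 1.81 against 6.75 ± 0.527 in ND zygotes.

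The diet comparison of GV oocytes addressed how the diet of the female changes the transcripts stored before maturation. HFD oocytes (n = 4) held more RNA of ribosomal proteins and of the nuclear-encoded respiratory chain than ND oocytes (n = 3), as lists with adjusted p = 0.941 with an estimated correlation. Wtap, a subunit of the RNA m6A methyltransferase, was at 269 ± 31.7 FPKM against 29.9 ± 9.21, and Alkbh5, an m6A demethylase, at 257 ± 13.1 against 84.9 ± 4.33. Kdm6b, a demethylase of histone H3 lysine methylation, was at 56.9 ± 4.77 against 14.8 ± 1.33. The ubiquitin gene Ubb fell from 6460 ± 326 to 3760 ± 99.7 FPKM.

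The 8 largest rises were Wtap (ENSMUSG00000060475, chromosome 17, 12966796 to 12992546, log2 fold change 3.16 ± 0.17), Pdcd4, Kdm6b, Kdelr2, Ric1, Alkbh5, Utp18 and Pdpn. Kdelr2, a receptor that returns proteins to the endoplasmic reticulum, was at 275 ± 19.2 against 80.8 ± 18.9 FPKM, and Pdcd4, an inhibitor of translation, at 46.6 ± 5.75 against 11.2 ± 2.07. The 8 largest falls were CT010467.1, mt-Co1, Mtfr2, Igf1os, Rimkla, Ubb, mt-Cytb and Obox7. By limma, adjusted p of these 16 genes ran from 5.24e-06 (Alkbh5) to 0.0151 (mt-Cytb). Of 74 ribosomal protein genes, 50 rose and 2 fell (54 and 3 adjusted over the list alone), with a median of 0.52, a camera adjusted p of 3.14e-11, adjusted p = 0.941 with an estimated correlation, and a fry adjusted p of 0.0015. Rps21 rose by 1.90, Rpl35 by 1.21, Rps12 by 1.17 and Rplp1 by 0.82. Of 62 nuclear genes of the respiratory chain, 41 rose and 2 fell (44 and 2 adjusted over the list alone), with a median of 0.43, a camera adjusted p of 3.63e-09 and adjusted p = 0.941 with an estimated correlation. Ndufa2 rose by 1.20, Ndufa1 by 1.14, Cox5a by 0.90 and Cox4i1 by 0.78. Acox1 was at 6.15 ± 0.53 FPKM against 5.6 ± 0.543 (limma adjusted p 0.445) and Abcd3 at 1.38 ± 0.129 against 1.13 ± 0.173 (0.343).

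Limma called 2665 of 10587 genes, 2134 higher and 531 lower, and 150 of them changed at least 2-fold (136 higher, 14 lower). Of the called genes 80.1% were higher, and 55.2% of 2331 with median-of-ratios scaling, which moved all genes by 0.125 on the log2 scale and left both lists higher. Mitochondrial transcripts took 1.47 ± 0.163% of FPKM in HFD and 2.25 ± 0.595% in ND oocytes, the 10 top genes 9.82 ± 0.0526 and 13.1 ± 0.66%, and ribosomal protein genes 1.33 ± 0.0574 and 1.17 ± 0.0569%. Genes at 1 FPKM or more numbered 10707 ± 92.1 and 10371 ± 140. In these 4 measures the groups did not overlap (exact permutation p 0.0571, adjusted 0.129, for each). All ND libraries came from another table than the HFD libraries, so diet and table cannot be told apart here, though no label names a batch, and a fit of both diets and all stages in 1 model called 266 genes, and the test without a filter on low values 1627.

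The diet comparison of MII oocytes addressed the mature egg. HFD oocytes (n = 6) held less RNA of ribosomal proteins, ribosome biogenesis factors and the nuclear respiratory chain than ND oocytes (n = 6), and more mitochondrial RNA, as lists with adjusted p = 0.899 with an estimated correlation. Without the 3 HFD libraries that stood apart, ribosome biogenesis did not pass camera (adjusted p 0.0658). Mos, the kinase that holds the metaphase II arrest, was at 119 ± 132 FPKM against 314 ± 13.4, and Zar1 at 38.0 ± 45.6 against 156 ± 23.2. Tle6, a member of the subcortical maternal complex, was at 33.7 ± 40.8 against 172 ± 33.6. Fth1, the ferritin heavy chain, rose from 35.6 ± 25.4 to 945 ± 702 FPKM, and all 12 mitochondrial DNA genes of the respiratory chain rose, also adjusted over the list alone.

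HFD replicates 1, 3 and 4 held 24.4, 18.5 and 19.2% of their FPKM in mitochondrial DNA genes, replicates 2, 5 and 6 held 12.3, 6.18 and 9.1%, and ND libraries 3.21 to 4.69%. The group means were 15.0 ± 6.92 and 4.09 ± 0.55%. Genes at 1 FPKM or more numbered 8140 ± 481 in HFD and 8832 ± 80.1 in ND libraries, and the 10 top genes took 23.6 ± 5.04 and 16.4 ± 0.312% of FPKM. Ribosomal protein genes took 0.118 ± 0.07 and 0.262 ± 0.0133%. The groups did not overlap in these 4 measures, each with an exact permutation p of 0.00216 (2-sided, adjusted 0.0244), the only 4 of 45 such tests with an adjusted p under 0.05. Genes called at least 2-fold lower had a median log2 fold change of -2.38 in HFD replicates 1, 3 and 4 and of -0.50 in replicates 2, 5 and 6.

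**Figure D3:**
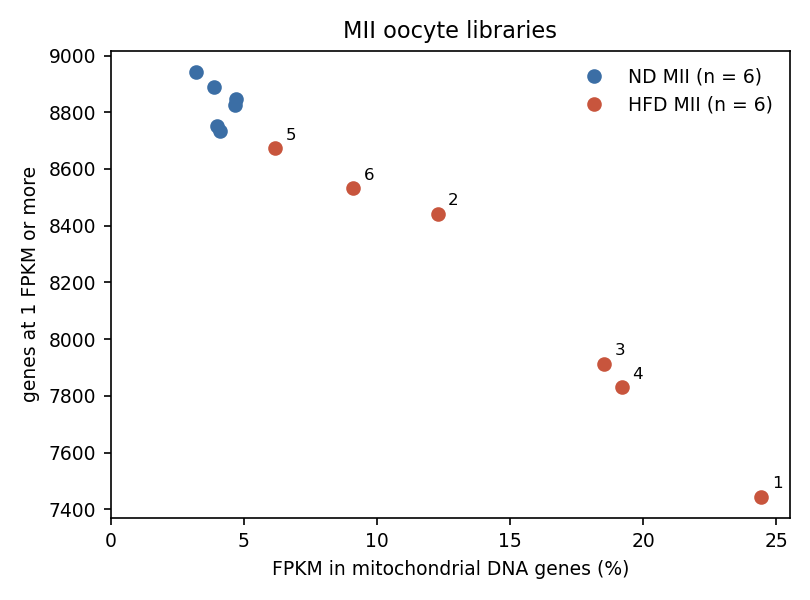
Share of FPKM in mitochondrial DNA genes (x axis, percent) against the number of genes at 1 FPKM or more (y axis) in each of the 12 MII libraries, coloured by diet. HFD libraries lie at 6.18 to 24.4% and ND libraries at 3.21 to 4.69%.

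The 8 largest rises in HFD MII oocytes were Fth1 (ENSMUSG00000024661, chromosome 19, 9982703 to 9985092, log2 fold change 4.39 ± 0.60), Selenow, Apitd1, Cript, BB557941, Xlr3a, mt-Rnr1 and Naca. The 8 largest falls were Plat, Mos (ENSMUSG00000078365, chromosome 4, 3870657 to 3872105, -4.17 ± 1.52), Zar1, Ube2t, Slc25a17, Taldo1, Bub1b and Tle6. Plat, the tissue plasminogen activator, was at 102 ± 119 against 374 ± 43.9 FPKM, Bub1b, a spindle checkpoint kinase, at 93.1 ± 101 against 286 ± 15.3, and Slc25a17, a peroxisomal carrier, at 61.5 ± 69.6 against 163 ± 3.4. By limma, adjusted p of these 16 genes ran from 0.00315 (Fth1) to 0.0365 (Mos). The 12 mitochondrial DNA genes had a median of 1.81 and a camera adjusted p of 4.69e-08, with mt-Co1 at 9840 ± 4250 against 2620 ± 481 FPKM and mt-Nd1 at 9360 ± 4780 against 2400 ± 300. Of 43 nuclear respiratory chain genes 1 rose and 27 fell (2 and 29 adjusted over the list alone, camera adjusted p 0.00403), such as Uqcr11 (-1.71) and Ndufa5 (-1.93). Of 36 ribosomal protein genes 23 fell (24 adjusted over the list alone, 0.000916), such as Rps6 (-1.16) and Rps28 (-0.87), and of 54 ribosome biogenesis genes 2 rose and 33 fell (2 and 36 adjusted over the list alone, 0.00751), such as Utp3 (-1.38) and Noc4l (-1.68). Of 24 genes of the endoplasmic reticulum stress response 1 rose and 15 fell, also adjusted over the list alone (0.0226), such as Sdf2l1 (-1.81) and Manf (-1.95). These 5 lists each had adjusted p = 0.899 with an estimated correlation. Of 58 maternal-effect and oocyte genes 10 rose and 31 fell (13 and 32 adjusted over the list alone), and the list did not pass camera (adjusted p 0.717).

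Limma called 4774 of 8723 genes, 1527 higher and 3247 lower, and 1954 changed at least 2-fold (371 higher, 1583 lower). Acox1 was at 6.71 ± 1.45 FPKM in HFD against 8.28 ± 0.875 (limma adjusted p 0.0883), and Abcd3, at 0.291 ± 0.118 against 0.455 ± 0.0656 FPKM, was not tested. Without HFD replicates 1, 3 and 4 limma called 2950 genes, 924 of them higher. The log2 fold changes were then 3.16 for Fth1, -0.40 for Mos, -1.12 for Zar1, -1.49 for Tle6 and 1.25 for mt-Co1, and Acox1 fell by 0.35 (limma adjusted p 0.0238). Ribosomal proteins (median -0.33, camera adjusted p 0.00478), the nuclear respiratory chain (-0.32, 0.00726) and mitochondrial DNA genes (1.17, 7.21e-08) then passed camera, with adjusted p = 0.732 with an estimated correlation for each, while ribosome biogenesis (-0.23, 0.0658) and the endoplasmic reticulum stress response (-0.20, 0.0775) did not. Falls numbered 18 of 37, 17 of 46, 20 of 55 and 9 of 25 in the ribosomal protein, respiratory chain, ribosome biogenesis and stress response lists. Both diets share a table, but the sample records of the HFD MII libraries are numbered apart from those of all other libraries, so a batch of their own stays possible.

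The diet comparison of 2-cell embryos addressed the stage at which the embryonic genome becomes active. HFD embryos (n = 8) held more RNA of ribosomal proteins, ribosome biogenesis factors and the nuclear-encoded respiratory chain than ND embryos (n = 3), and less RNA of oocyte genes, as lists with adjusted p = 0.556 with an estimated correlation. Control embryos of the knockdown series lay apart from ND embryos in the same direction. Their mean log2 level of ribosome biogenesis genes was 4.72 to 5.26 (HFD 3.86 to 4.84, ND 3.25 to 3.64) and that of oocyte genes 5.39 to 5.86 (HFD 5.42 to 6.37, ND 6.34 to 6.66). Rpl35 was at 10.5 ± 2.52 FPKM against 0.317 ± 0.13 and Rps19 at 14.1 ± 2.96 against 2.01 ± 0.571. Nlrp4f and Nlrp14, oocyte genes of the NLR family, were at 92.8 ± 35.0 against 302 ± 57.6 and at 131 ± 33.5 against 306 ± 54.4 FPKM. Acox1 was at 20.7 ± 2.46 FPKM against 16.3 ± 1.81 (limma adjusted p 0.168), and Abcd3, at 0.223 ± 0.155 against 0.157 ± 0.0618 FPKM, was not tested.

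The 8 largest rises were Rab29 (ENSMUSG00000026433, chromosome 1, 131867224 to 131872887, log2 fold change 2.75 ± 0.35), Gm2a, AC122327.4, Sat1, Snhg15, Supt4a, Atg101 and Mt1. Gm2a, the activator of ganglioside breakdown, was at 228 ± 108 against 34.4 ± 7.43 FPKM, Sat1, which acetylates polyamines, at 43.4 ± 27.5 against 6.71 ± 1.24, and the metallothionein Mt1 at 125 ± 54.5 against 24.8 ± 9.37. The 8 largest falls were Obox7 (ENSMUSG00000055942, chromosome 7, 14659496 to 14665996, -2.30 ± 0.32), Rfpl4, AC154747.3, AC112259.2, Nlrp4g, Nlrp4f, Izumo1r and Dnajb4. Obox7, an oocyte homeobox gene, was at 45.5 ± 17.8 against 222 ± 74.1 FPKM, and Izumo1r, the oocyte receptor for sperm, at 9.59 ± 2.85 against 34.1 ± 11. By limma, adjusted p of these 16 genes ran from 0.000439 (Supt4a) to 0.0103 (Rfpl4).

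Of 77 ribosomal protein genes 60 rose and 1 fell (66 and 1 adjusted over the list alone), with a median of 1.32 and a camera adjusted p of 1.05e-20, and Rps5 rose by 2.50 and Rpl18a by 2.41. Of 72 ribosome biogenesis genes 37 rose and 0 fell (55 and 0 adjusted over the list alone, median 0.87, camera adjusted p 1.05e-10), such as Imp3 (1.89), Nop10 (1.66), Nop56 (1.48) and Rrn3 (1.48), an initiation factor of RNA polymerase I. Of 61 nuclear respiratory chain genes 31 rose and 1 fell (38 and 1 adjusted over the list alone, 0.76, 8.99e-08), such as Ndufa2 (2.58) and Uqcr10 (2.41). Of 59 oocyte genes 4 rose and 24 fell (4 and 29 adjusted over the list alone, -0.60, 7.55e-09), with Nlrp4a (-1.62) lower and Uchl1 (1.12), a ubiquitin hydrolase, higher. Of 52 minor ZGA genes 6 rose and 9 fell (7 and 13 adjusted over the list alone, -0.41, 0.00331), with Gm4850 (2.05) and Arg2 (1.34) higher and Gm21319 (-1.43) and B020031M17Rik (-1.14) lower. Each of these 5 lists had adjusted p = 0.556 with an estimated correlation. With ND and control embryos together as the normal group ribosome biogenesis did not pass (2 rose, median 0.05, camera adjusted p 0.98). Ribosomal proteins (0.72, 1.71e-08), the nuclear respiratory chain (0.82, 6.82e-16), minor ZGA genes (-0.47, 7.75e-08) and oocyte genes (-0.21, 0.0366, 3 rose and 1 fell) still passed, with adjusted p = 0.813, adjusted p = 0.126, adjusted p = 0.126 and adjusted p = 0.813 with an estimated correlation. Ribosomal protein genes took 1.54 ± 0.449% of FPKM in HFD and 0.727 ± 0.0945% in ND libraries, and genes at 1 FPKM or more numbered 13187 ± 416 and 12155 ± 269. Both measures had an exact permutation p of 0.0121 (adjusted 0.0765).

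Of the lists on the subject of the series, 2 of 16 peroxisomal beta-oxidation genes rose, Decr2 (1.89) and Scp2 (0.97), and 1 adjusted over the list alone (camera adjusted p 0.98), while Slc25a17 (0.50, adjusted p 0.148 by limma) and Slc27a2 (-1.16, 0.158) did not pass, nor did Scp2 without HFD replicates 3 and 6 (adjusted p 0.0898 by limma). Of 27 methionine and one-carbon genes 3 rose and 2 fell (4 and 3 adjusted over the list alone, 0.98), with Apip (0.71) and Tyms (1.21) higher and Mtap (-1.15), the first enzyme of methionine salvage, and Cth (-0.69) lower. For both lists the median was above 0 (0.24 and 0.32) while camera ranked them down against other genes. Of 30 phospholipid synthesis genes 5 rose and 1 fell, also adjusted over the list alone (0.765), with Pemt (1.38), which methylates phosphatidylethanolamine, Ptdss2 (1.51) and Pcyt2 (1.06) higher and Cept1 (-1.02) lower. Pemt was at 29.6 ± 9.44 FPKM in HFD against 10.4 ± 2.03 in ND embryos. Pcyt2 turned to -0.209 (limma adjusted p 0.867) with ND and control embryos together as the normal group. Of 36 histone methyltransferase genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, 0.538), with Kmt2d (1.04), Kmt5a (0.93) and Dot1l (0.79) higher and Eed (-0.83), a subunit of Polycomb complex PRC2, lower.

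Because ND 2-cell libraries enter this comparison, activation and decay lists were taken from control 2-cell embryos against ND zygotes. In both lists controls lay on the HFD side of ND, so the lists can lean toward a difference of HFD from ND. Of 2358 activation genes 866 rose and 40 fell in HFD embryos, with a median of 0.76, a camera adjusted p of 1.34e-15 and adjusted p = 0.138 with an estimated correlation. Of 869 decay genes 30 rose and 198 fell, with a median of -0.49, a camera adjusted p of 1.94e-23 and adjusted p = 0.0354 with an estimated correlation. With the lists from ND 2-cell embryos against ND zygotes, which share libraries with this comparison, activation genes had a camera adjusted p of 0.0188 and adjusted p = 0.562 with an estimated correlation. Of 333 decay genes 52 rose and 23 fell, so their median turned to 0.11, with a fry adjusted p of 0.0169 upward, while camera ranked them down (adjusted p 0.593). Limma called 2903 of 13211 genes, 2166 higher and 737 lower, and 1733 changed at least 2-fold (1339 higher, 394 lower). Of the called genes 74.6% were higher, and 51.3% of 2946 with median-of-ratios scaling, which moved all genes by 0.252 on the log2 scale. The count was 647 without ND replicate 1, 1520 without ND replicate 2 and 1446 without ND replicate 3, 1043 with ND and control embryos together as the normal group, 1846 without a filter on low values and 4613 with all diet libraries in 1 fit. HFD replicate 3 lay apart in cumulus markers (3.54 on the mean log2 scale, other HFD libraries 1.78 to 2.07) and replicate 6 was highest in blood markers (3.21, others 1.96 to 2.56), and without both the count was 1931. The files of HFD and ND libraries list different genes, but a single deposited table holds both with the same values, so the table does not separate the diets here. No label names a batch, and a batch that goes with diet was not tested.

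The fold changes of siAcox1 against control and of HFD against ND 2-cell embryos, which share no library, ran in opposite directions across genes. Over 11544 genes Pearson r was -0.595 (permutation p 0.0206 over 3300 relabellings of the libraries) and Spearman rho was -0.629 (permutation p 0.02). Over the 2733 of these genes called for HFD, as none was called for siAcox1 without pairs, r was -0.68 (permutation p 0.077). With siAcox1 and control exchanged only within pairs, a test chosen after the result was seen, the permutation p was 0.0227 (15 of 660 relabellings), but there are only 4 such exchanges, and another of them gave an absolute r of 0.594 with the diet labels kept. Genes are not independent replicates, so these p values come from relabelled libraries. Among genes called in both, with pairs for siAcox1, 572 were lower in siAcox1 and higher in HFD (256 if independent) and 261 were higher in siAcox1 and lower in HFD (62.4 if independent). In the same direction, 26 were higher in both (183 if independent) and 1 was lower in both (87.3 if independent). Without ND 2-cell replicate 1 the r was -0.552 (permutation p 0.0511). The siAcox1 fold changes followed the main axis of the deviations within the diet groups at the 2-cell stage (absolute r 0.643). Those of HFD followed the main axis within the knockdown groups (absolute r 0.671). A difference in the timing or state of the embryos could therefore also give such a correlation.

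**Figure D4:**
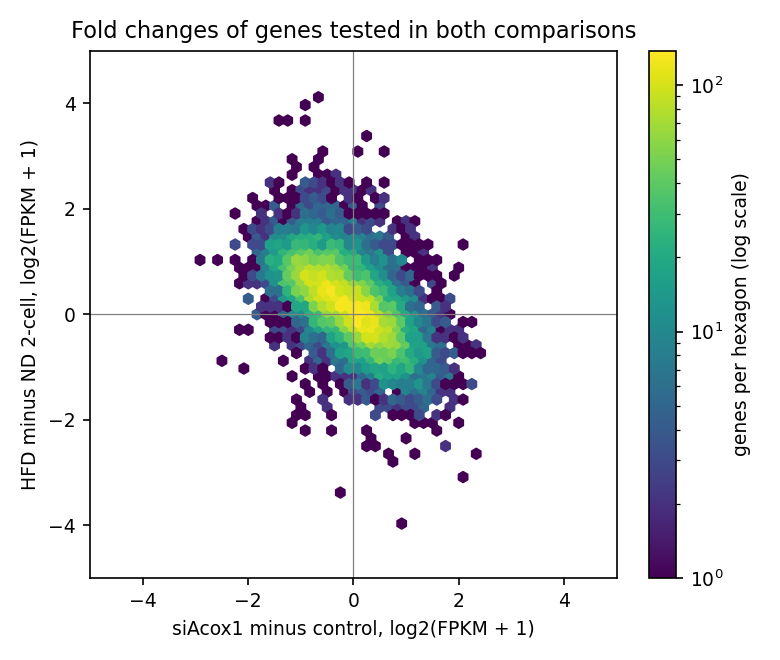
Log2 fold changes of FPKM + 1 in siAcox1 against control (x axis) and in HFD against ND 2-cell embryos (y axis) for 11544 genes, with colour for the number of genes per hexagon on a log scale. The cloud slopes downward, with a Pearson r of -0.595.

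The test of the difference between diet effects asked whether HFD changes 2-cell embryos differently from GV oocytes. Because ND and HFD GV libraries came from different tables, a difference of diet effects cannot be told apart from one of table. As lists, ribosome biogenesis genes (median difference 0.81 over 72 genes, camera adjusted p 8.22e-11) and ribosomal protein genes (0.85 over 76, 1.89e-11) had a higher, and oocyte genes (-0.71 over 60, 1.78e-07) a lower diet effect at the 2-cell stage than at GV, each with adjusted p = 0.705 with an estimated correlation. Rab29 had a difference of 2.89 and Rpl35 of 1.89, and Wtap (-1.45) and Izumo1r (-2.26) differed the other way. Of 72 ribosome biogenesis genes 12 rose and 1 fell in this test, of 76 ribosomal protein genes 19 rose and 0 fell, and of 60 oocyte genes 1 rose and 9 fell. Limma called 1051 of 13019 genes, 608 higher and 443 lower, and 1815 with both copies of the ND GV library. Limma-voom called 817, with 327 higher and 490 lower, so the more frequent direction turned. Without 1 library the count ran from 268 (ND 2-cell replicate 1) to 1894 (HFD 2-cell replicate 2), and without a filter on low values it was 518, with 243 higher.

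Across normal development, the step from GV to MII oocytes addressed meiotic maturation. ND MII oocytes (n = 6) had a far lower share of RNA of ribosomal proteins and of the nuclear respiratory chain than ND GV oocytes (n = 3). Their share of mitochondrial RNA was higher. As lists these had adjusted p = 0.52, adjusted p = 0.52 and adjusted p = 0.575 with an estimated correlation. Rps27a fell from 89.2 ± 2.07 to 1.29 ± 0.289 FPKM, and Cox4i1 from 45.9 ± 3.8 to 0.919 ± 0.179. mt-Nd2 rose from 255 ± 75.3 to 917 ± 94.6 FPKM, and Acox1 from 5.6 ± 0.543 to 8.28 ± 0.875 (limma adjusted p 0.000416).

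The largest rises were AA619741, Ppp3r1, Ncoa4, Yaf2, Wtap, Fam160a1, Lin7c and AC159312.1, and the largest falls Upp1, Fam162a, Fcf1, Ckb, Bud31, Cpsf4l, Rnaset2a and Timm17a. Upp1 (ENSMUSG00000020407, chromosome 11, 9118103 to 9136170), a uridine phosphorylase, fell from 266 ± 0.664 to 1.76 ± 0.547 FPKM (-6.61 ± 0.15, limma adjusted p 2.23e-15), and Ckb, the brain creatine kinase, from 117 ± 15.0 to 1.45 ± 0.527. Ppp3r1, the regulatory subunit of calcineurin, rose from 11.8 ± 1.78 to 63.2 ± 2.79 FPKM. Of 66 ribosomal protein genes 63 fell and 1 rose, also adjusted over the list alone, with a median of -2.71, a camera adjusted p of 5.38e-17 and adjusted p = 0.52 with an estimated correlation. Rpl7a fell by 5.0 and Rpl4 by 3.15. Of 59 nuclear respiratory chain genes 54 fell and 5 rose, also adjusted over the list alone, with a median of -2.08, a camera adjusted p of 4.63e-10 and adjusted p = 0.52 with an estimated correlation. All 12 mitochondrial DNA genes rose, also adjusted over the list alone, with a median of 1.09, a camera adjusted p of 0.000528 and adjusted p = 0.575 with an estimated correlation. Limma called 7695 of 10881 genes, 3214 higher and 4481 lower, and 3355 changed at least 2-fold (759 higher, 2596 lower). ND GV and ND zygote libraries came from 1 deposited table and ND MII and ND 2-cell libraries from 2 others, so stage and table go together in all 3 steps of this course, though no label names a batch.

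The step from MII oocytes to zygotes addressed fertilisation. Mos fell from 314 ± 13.4 to 11 ± 0.879 FPKM in zygotes (n = 3), and Plat from 374 ± 43.9 to 33.5 ± 3.48. Eef1a1, the translation elongation factor, rose from 23.2 ± 2.67 to 280 ± 16.5 FPKM, and Tubb4b, a beta-tubulin, from 9.15 ± 1.25 to 80.5 ± 9.21. Acox1 fell from 8.28 ± 0.875 to 6.75 ± 0.527 FPKM (limma adjusted p 0.0392). The largest rises were Aven, Eef1a1 (ENSMUSG00000037742, chromosome 9, 78478449 to 78489151, 3.54 ± 0.11), Elof1, Fth1, Copz1, Tubb4b, Stx5a and Sh3bgrl3, and the largest falls Mos (-4.71 ± 0.10), Saraf, Leprot, Fbxl6, Erp44, Tpra1 and Plat. No list passed camera, where ribosome biogenesis (37 of 66 rose, 3 fell) and oocyte genes (18 of 59 rose, 26 fell) both had an adjusted p of 0.0689. Limma called 6697 genes, 4332 higher and 2365 lower, and 1865 changed at least 2-fold (1355 higher, 510 lower). Of the called genes 64.7% were higher, and 54.8% with median-of-ratios scaling, which moved all genes by 0.161.

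The step from zygote to 2-cell embryo holds the activation of the embryonic genome. Zfp352, a gene of the 2-cell stage, rose from 0.312 ± 0.291 FPKM in zygotes (n = 3) to 357 ± 16.9 in 2-cell embryos (n = 3), and the homeobox gene Obox6 from 0.352 ± 0.317 to 506 ± 152. Dnmt1, the maintenance DNA methyltransferase, fell from 243 ± 25.4 to 9.45 ± 0.8 FPKM, and Txnip, a thioredoxin-binding protein, from 193 ± 15.2 to 11.7 ± 1.25. Acox1 rose from 6.75 ± 0.527 to 16.3 ± 1.81 FPKM (1.15 ± 0.12, limma adjusted p 1.7e-07). Abcd3 was at 1.26 ± 0.0474 FPKM in zygotes and 0.157 ± 0.0618 in 2-cell embryos and was not tested.

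The largest rises were Obox6, Trim43b, Zfp352 (ENSMUSG00000070902, chromosome 4, 90218820 to 90225702, 8.12 ± 0.13), AC126554.8, Prps1, Bex6, AF067063 and Gcsh, and the largest falls Dnmt1 (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888, -4.54 ± 0.13), Bms1, Txnip, Edrf1, Gja4, Rgs2, Ssb and Tacc3. Of 50 minor ZGA genes 45 rose and 3 fell, also adjusted over the list alone, with a median of 4.57, a camera adjusted p of 3.92e-17 and adjusted p = 0.0864 with an estimated correlation. Gm8300, Gm5662 and B020004C17Rik rose to 252 ± 39.7, 190 ± 34.0 and 367 ± 79.3 FPKM. Of 66 ribosomal protein genes 55 rose and 4 fell, also adjusted over the list alone (median 1.18, camera adjusted p 1.43e-08), such as Rplp0 (2.81) and Rps3 (4.05). Of 59 oocyte genes 12 rose and 42 fell, also adjusted over the list alone (median -1.06, 9.78e-05), with Zar1l (-2.64) and Cpeb1 (-2.44), a regulator of maternal RNA translation, lower and Tcl1b4 (1.89) higher. Of 12 mitochondrial DNA genes 11 rose, also adjusted over the list alone (1.95, 0.000614), such as mt-Nd1 (2.57). These 3 lists each had adjusted p = 0.534 with an estimated correlation. Limma called 8000 of 10881 genes, 3926 higher and 4074 lower, and 3899 changed at least 2-fold (2124 higher, 1775 lower). Of the called genes 49.1% were higher, and 57.6% of 7945 with median-of-ratios scaling, which moved all genes by -0.213. Without a filter on low values 14564 genes were called, 10123 of them higher.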

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

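The tests of library composition, of siAcox1 replicate 2 alone, of the shared controls, of transcripts that fall after MII, of exchanges within pairs and of cell markers per library were chosen after the results were seen.

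Ribosomal protein and respiratory chain genes were higher in HFD GV oocytes (median 0.50 on the log2 scale over 136 genes) and in HFD 2-cell embryos (1.16 over 138 genes), where each list had adjusted p = 0.941 and adjusted p = 0.556 with an estimated correlation. The tables argue against library composition as the whole cause, since after median-of-ratios scaling the medians were 0.373 (0.28 to 0.464) and 0.933 (0.805 to 1.058). Gene length may account for a part, and stays open, because genes matched on exon length and FPKM reached 33.9% (28.6 to 41.8) of the median at GV and 22.3% (19.1 to 27.7) at the 2-cell stage. At the 2-cell stage the diet effect also followed the axis along which replicate knockdown and control libraries differ (absolute r across genes 0.671, 0.616 to 0.672). Embryo timing or state could thus give such a pattern, though this was not tested for the respiratory chain. The diet itself remains open. Controls lay nearer HFD in ribosome biogenesis but near ND in the respiratory chain (2.67 to 3.02, ND 2.72 to 2.85). At GV the diets came from different tables, so diet and table cannot be told apart. No batch was named or tested.

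In siAcox1 embryos ribosome biogenesis transcripts were lower and oocyte transcripts higher than in controls, as lists with adjusted p = 0.919 with pairs and adjusted p = 0.96 without with an estimated correlation, while 0 genes were called without pairs and 0 of the 2577 paired calls remained without pair 1, without pair 2 or with only the 2 groups in the fit. The tables argue against siAcox1 replicate 2 as the whole cause, since without it the median of the ribosome biogenesis list was -0.696 (-0.814 to -0.548), against -0.939 to -1.317 without any other siAcox1 or control library. The fold changes followed the main axis of deviations within the 2-cell diet groups (absolute r across genes 0.643, 0.582 to 0.65). Embryo timing or state could also give this pattern. Chance values of the shared controls stay open. A covariance as large as the 0.272 observed arose in 65 of 1000 simulations (middle 95% -0.066 to 0.384) and in 13 with pairs kept. Both lists also shifted in siAbcd3 embryos (paired medians -0.50 and 0.63), where no lower Abcd3 was seen. An Acox1-specific effect remains a hypothesis.

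In HFD MII oocytes 3247 genes were lower and the mitochondrial share was higher, most of all in replicates 1, 3 and 4, and both diets came from 1 table while the HFD sample records are numbered apart. The tables argue against dilution by mitochondrial transcripts, since without them the 1583 genes called at least 2-fold lower had a median of -1.407 (-1.431 to -1.377) against -1.446 before. Gene length is argued against as well, with a Spearman correlation of fold change and exon length of -0.001 (-0.01 to 0.011). Loss of the transcripts that normally fall after MII, as aged or activated oocytes might show, stays open. The genes at least 2-fold lower had a median of -0.419 (-0.466 to -0.38) from ND MII oocytes to ND zygotes, between the bounds set for and against it. Of them 23.8% were also at least 2-fold lower in ND zygotes, against 5.92% of all tested genes. Across genes, Pearson r with this step was 0.419 to 0.437 in HFD replicates 1, 3 and 4 and 0.145 to 0.3 in replicates 2, 5 and 6. Both changes start from ND MII oocytes, which can raise such values. An effect of the diet on the mature oocyte and a batch of the HFD libraries were not tested apart from such a loss and remain open.

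For the counts of called genes in 6 comparisons, 1 split of the libraries, the real one, gave as many genes, a share under 0.05. This argues against a random grouping of like libraries but does not exclude it, as the shares were not adjusted over the comparisons. It does not tell diet or stage apart from anything else that differs between the groups. The real count and the highest of the other splits were 2665 and 1 for diet in GV oocytes (35 splits), 4774 and 0 in MII oocytes (100 splits), 2903 and 7 in 2-cell embryos (100 splits) and 1051 and 9 for the difference between the diet effects (100 splits). They were 7695 and 0 for MII against GV and 6697 and 1 for zygotes against MII oocytes (84 splits each). The splits were too few for a share under 0.05 in the knockdown comparisons (10 splits each, 0 and 0 genes), for 2-cell embryos against zygotes (10 splits, 8000 and 1) and for the paired siAcox1 fit (4 exchanges within pairs, 2577 and 0).

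In 11 of 238 groups of values 1 library lay far from the rest, and chance alone gives about 1 in 20. HFD GV replicate 3 had 20.2 M reads against 15.8 to 16.3 in the other HFD GV libraries. ND MII replicate 1 had 21.2 FPKM of Copz1 against 17.5 to 18.5, replicate 5 had 87.3 FPKM of Fth1 against 22.3 to 29.8, and replicate 3 had 2.79 FPKM of Upp1 against 1.32 to 1.83. The mean log2 level of blood markers was 1.26 in ND MII replicate 5 against 0.178 to 0.382, that of cumulus markers 3.54 in HFD 2-cell replicate 3 against 1.78 to 2.07, and that of sperm markers 2.34 in HFD 2-cell replicate 5 against 2.76 to 3.12. HFD MII replicate 3 had 9.55 FPKM of Acox1 against 5.71 to 6.78, and HFD MII replicate 5 had 1.66 FPKM of Uqcr11 against 0 to 0.292. HFD 2-cell replicate 2 had 15.1 FPKM of Acox1 against 20 to 23.4, and HFD 2-cell replicate 8 had 503 FPKM of Gm4850 against 247 to 356.

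The diet effect differed between the 2-cell stage and GV for 1051 genes by a test of the difference itself. ND and HFD GV libraries came from different tables, so such a difference cannot be told apart from one of table. As lists, ribosome biogenesis (adjusted p 8.22e-11, median 0.81), ribosomal proteins (1.89e-11, 0.85) and oocyte genes (1.78e-07, -0.71) differed, each with adjusted p = 0.705 with an estimated correlation. Among genes named in the text the effect at the 2-cell stage minus that at GV, on the log2 scale, was above 0 for Fgf4 (2.95), Rab29 (2.89), Mt1 (2.07), Gm2a (2.03), CT010467.1 (2.0), Atg101 (1.99), Snhg15 (1.97), Rpl35 (1.89), Decr2 (1.80), Gm4850 (1.76), Supt4a (1.68), Cdkn1a (1.65), Rps19 (1.64), Uqcr10 (1.63), Rps5 (1.60), Mtfr2 (1.58), Rpl18a (1.53), Btg2 (1.52), Ndufa2 (1.38), Nop56 (1.36), Cyp51 (1.35), Ptdss2 (1.33), Creld2 (1.24), Rrn3 (1.22), Ubb (1.02), Gpx4 (0.99) and Arg2 (0.96). It was below 0 for Izumo1r (-2.26), Dnajb4 (-2.1), Fabp5 (-2.09), AC154747.3 (-1.77), Nlrp4g (-1.76), Nlrp4f (-1.71), Obox7 (-1.59), Gata3 (-1.56), Wtap (-1.45), Gm21319 (-1.43), Mtap (-1.23), Lpl (-1.2), Nlrp14 (-1.14), Cept1 (-1.08), Utp18 (-0.69) and Ric1 (-0.61). By limma the adjusted p of these 43 genes ran from 0.000899 (Rpl35) to 0.0493 (Ptdss2).

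In some lists every HFD library lay above the ND mean at one stage and below it at another, and these differences were not tested. The mean log2 level of ribosomal proteins changed by 0.51 at GV and -0.57 at MII (difference 1.08) and that of the nuclear respiratory chain by 0.44 and -0.64 (1.09). Between MII and the 2-cell stage the changes were -0.57 and 1.31 for ribosomal proteins (difference -1.87), -0.64 and 0.82 for the nuclear respiratory chain (-1.47) and -0.72 and 0.91 for ribosome biogenesis (-1.64). Without HFD MII replicates 1, 3 and 4 the same MII changes were -0.23 for ribosomal proteins, -0.32 for the nuclear respiratory chain and -0.20 for ribosome biogenesis.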

How the results depend on the processing

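The alternatives chosen after seeing the data were limma-voom, genes listed in all files, leaving out HFD MII replicates 1, 3 and 4 or HFD 2-cell replicates 3 and 6, lists of the 2-cell stage with controls in the normal group, exchanges within pairs and those of the paired siAcox1 fit, and the others were fixed before the data were examined. Not run were the DESeq2 Wald test and the quasi-likelihood test with relative log expression factors, which need counts, while limma-trend and scaling by library size are what the values already carry. Over all alternatives, 227 results of comparisons and lists as a whole stayed the same (counts within 1.5 times in either direction, p values on the same side of the threshold), 11 no longer passed and 61 values moved. Of named genes in single alternatives 3871 results kept their side of the threshold and, if past it, their direction, 217 no longer passed, 33 passed anew and 4 reversed, and of single lists 751 kept both, 84 passed anew and 45 no longer passed. Unless said otherwise, the cause was not tested.

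With an absolute log2 fold change of at least 1, a stricter criterion by construction, limma called 150 genes for diet in GV oocytes, 1954 in MII oocytes and 1733 in 2-cell embryos, 3355 for MII against GV, 1865 for zygotes against MII, 3899 for 2-cell embryos against zygotes and 1521 in the paired siAcox1 fit. Without a filter on low values, which adds genes to the test, the counts were 1627 for GV, 1846 for 2-cell embryos, 14564 for 2-cell embryos against zygotes, 518 for the difference between diet effects and 0 for paired siAcox1. The replicate number as a block gave 2577 genes for siAcox1, passed 5 lists by fry there, changed no other count or camera call of the knockdowns, and gave 1055 for diet in 2-cell embryos, where the number was not shown to link libraries. Fits with only the groups compared gave 1 gene for siAcox1 against siAbcd3 and 0 for paired siAcox1. All diet libraries in 1 fit gave 266 genes for GV and 4613 for 2-cell embryos. ND and control embryos together as the normal group gave 1043 genes and 8 lists, and Pcyt2 reversed to -0.209, Sc5d to 0.213, Trib3 to -0.321 and Kdm5b to -0.098. Both copies of the identical ND GV library gave 1815 genes for the difference between diet effects. Without HFD MII replicates 1, 3 and 4 the MII count was 2950 and 3 lists passed, and without HFD 2-cell replicates 3 and 6 the 2-cell count was 1931.

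Leaving out 1 library gave 0 to 0 genes in the 3 unpaired knockdown comparisons, 1889 to 2887 for GV, 3274 to 5554 for MII, 7210 to 7623 for MII against GV, 6054 to 6566 for zygotes against MII and 7394 to 7729 for 2-cell embryos against zygotes. For diet in 2-cell embryos it gave 647 to 3458, with 647, 1520 and 1446 without ND replicates 1, 2 and 3. For the difference between diet effects it gave 268 to 1894, with 268 and 669 without ND 2-cell replicates 1 and 3, 358, 519 and 435 without ND GV replicates 1, 2 and 3, 567 to 598 without HFD GV replicate 1, 2, 3 or 4, and 1813 and 1894 without HFD 2-cell replicates 1 and 2. The paired siAcox1 count ran from 0 to 1253. The correlation across genes of siAcox1 and HFD fold changes ran from -0.634 to -0.430, was -0.552 (permutation p 0.0511) without ND 2-cell replicate 1, and over genes called for HFD it was -0.68 (permutation p 0.077), and with exchanges within pairs the permutation p was 0.0227. That of the knockdowns ran from 0.567 to 0.888.

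With an estimated correlation camera passed 0 lists in every comparison. It failed minor ZGA genes from zygotes to 2-cell embryos and ribosomal proteins from GV to MII, though most members were called. A list that fails it may still have changed. Fry, which tests each list on its own, passed 0 lists in each unpaired knockdown comparison, 11 for GV, 19 for MII, 18 for 2-cell embryos, 21 for MII against GV, 16 for zygotes against MII and 21 for 2-cell embryos against zygotes. Median-of-ratios scaling passed 1 list for zygotes against MII and 5 for the difference between diet effects. The p of activation genes was 0.264 in siAcox1 and 0.606 in siAbcd3 embryos with an estimated correlation and 0.107 and 0.602 by fry, and that of decay genes 0.0781 and 0.183 with an estimated correlation and 0.171 by fry in siAbcd3. In HFD embryos activation genes had a p of 0.138 with an estimated correlation, and decay genes of 0.593 with the list from ND 2-cell embryos. A pseudocount of 0.1, a mean of at least 100 recovered reads, voom and genes listed in all files kept every count of called genes within 1.5 times. The more frequent direction turned under voom for the difference between diet effects (327 of 817 higher), and so it did without a filter (243 of 518). For 2-cell embryos against zygotes it turned with median-of-ratios scaling (4576 of 7945 higher), without a filter (10123 of 14564), at 2-fold (2124 of 3899) and without ND zygote replicate 2 (3826 of 7593).

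At 9.01 to 21.37 M reads depth limits low genes, and Abcd3, at 0.496 ± 0.161 FPKM in controls, lay under the filter. The knockdown comparisons without pairs recovered 0 to 8% of simulated 2-fold rises.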

Other observations

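The genes named here were chosen after their values were seen, and none of the lists named here passed camera in the comparison given. In 2-cell embryos from HFD females 13 of 35 genes against oxidative stress rose and 2 fell (16 and 4 adjusted over the list alone, camera adjusted p 0.14). Sod1, the cytosolic superoxide dismutase, rose from 4.63 ± 0.939 to 21.7 ± 3.94 FPKM and Gpx4, a lipid peroxidase, from 13.9 ± 2.4 to 44.3 ± 11.7, while Prdx1, a peroxiredoxin, fell from 629 ± 68.2 to 323 ± 99.4. Of 21 cholesterol synthesis genes 9 rose and 2 fell (12 and 2 adjusted over the list alone, 0.0934), with Cyp51 (1.51 on the log2 scale) and Hmgcr (0.98) higher and Sc5d (-0.97) lower. Of 30 genes of the endoplasmic reticulum stress response 10 rose and 0 fell (13 and 0 adjusted over the list alone, 0.114), such as Creld2 (1.38) and Trib3 (1.16). Of 21 p53 targets 6 rose and 0 fell (8 and 1 adjusted over the list alone, 0.275), among them the cell cycle inhibitors Cdkn1a (1.53) and Btg2 (1.31). Of 20 histone demethylases 7 rose and 0 fell (8 and 0 adjusted over the list alone, 0.135), with Kdm6b at 19.5 ± 5.02 against 4.0 ± 1.2 FPKM and Kdm5b at 23.7 ± 5.36 against 14.2 ± 3.0. With ND and control embryos together as the normal group, Trib3 (-0.321), Sc5d (0.213) and Kdm5b (-0.098) turned and did not pass. The lists of oxidative stress (6 rose, camera adjusted p 0.0224), cholesterol synthesis (4, 0.0224), imprinted genes (2, 0.0366) and mitochondrial DNA genes (3, 0.0224) then passed, with adjusted p = 0.34, adjusted p = 0.539, adjusted p = 0.34 and adjusted p = 0.813 with an estimated correlation. Rises then numbered 1 of 31 in the stress response of the endoplasmic reticulum, 1 of 21 in p53 targets and 2 of 20 in demethylases.

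Of 21 genes of pluripotency and later cleavage 5 rose and 1 fell in HFD 2-cell embryos (camera adjusted p 0.159), with Fgf4, a growth factor, at 27.6 ± 11.9 against 2.79 ± 1.86 FPKM, Sall4 (1.18) higher and Gata3 (-1.26) lower. Of 19 genes of DNA methylation 4 rose and 1 fell (5 and 1 adjusted over the list alone, 0.375), with Dnmt3l (1.34) and Uhrf1 (1.21) higher and Zfp57 (-0.64), a keeper of imprints, lower, and of 15 imprinted genes 3 rose (0.216). In lipid metabolism 3 rose and 1 fell of 19 mitochondrial beta-oxidation genes (0.349), as did 3 and 1 of 20 fatty acid synthesis genes (3 and 3 adjusted over the list alone, 0.371), and 1 rose and 2 fell of 17 lipid droplet and uptake genes (0.724), the latter Fabp5 (-1.25) and Lpl (-1.04). Of 14 peroxisome biogenesis genes 3 rose and 0 fell (0.975), of 7 ether lipid genes 1 and 0 (0.98), of 35 maternal RNA decay factors 7 and 3 (0.98), and of 12 mitochondrial DNA genes 2 and 4 (4 and 5 adjusted over the list alone, 0.304). Ether lipid genes and decay factors had medians of 0.31 and 0.15 while camera ranked them down, and fatty acid synthesis genes a mean of 0.05 and a median of -0.003. Of markers of other cell types 2 of 10 cumulus genes (0.986), 1 of 4 sperm genes (0.975) and 2 of 6 blood genes (0.323) rose. HFD replicate 3 had a mean log2 level of cumulus markers of 3.54 (other HFD libraries 1.78 to 2.07, ND 1.62 to 1.89) and the highest of the nuclear respiratory chain (3.97), and replicate 6 had 3.21 for blood markers (others 1.96 to 2.56, ND 1.27 to 1.62). Without both, Zfp57 (-0.654, limma adjusted p 0.0573) and Kdm5b (0.679, 0.0862) did not pass. Where no second count is given, the count adjusted over the list alone was the same.

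In HFD MII oocytes 11 of 16 genes of DNA methylation fell and 0 rose (camera adjusted p 0.376), with Tet3 at 29.3 ± 26.2 against 80.1 ± 4.3 FPKM, Uhrf1 at 29.4 ± 29.0 against 67.8 ± 4.4 and Dnmt3a at 3.02 ± 2.13 against 6.59 ± 0.905. Of 12 lipid droplet genes 10 fell and 1 rose (0.0926), with Plin3 (-2.37) and Dgat2 (-1.91) lower and Abhd5 (0.48) higher. Of 21 methionine and one-carbon genes 11 fell and 0 rose (0.156), such as Mat2a (-0.76), which makes S-adenosylmethionine, and Mthfd1l (-1.34), and of 22 phospholipid synthesis genes 12 fell and 2 rose (16 and 2 adjusted over the list alone, 0.152), such as Lpcat1 (-2.74) and Ptdss1 (-0.74). The count adjusted over the list alone was the same for the other 3 lists. Without HFD replicates 1, 3 and 4, which stood apart, Dnmt3a (-0.379), Plin3 (-0.503), Dgat2 (-0.572), Abhd5 (0.146) and Mat2a (-0.312) did not pass, with limma adjusted p of 0.0522 to 0.362. Falls then numbered 7 of 15 DNA methylation, 2 of 12 lipid droplet, 5 of 22 methionine (0 adjusted over the list alone) and 8 of 23 phospholipid genes, and 0 rose.

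Across genes, the diet effect correlated between GV and the 2-cell stage with a Pearson r of 0.262 (9241 genes), between GV and MII with -0.026 (8306) and between MII and the 2-cell stage with -0.214 (8112), and that of siAbcd3 with HFD at the 2-cell stage with -0.534 (11544). Genes are not independent replicates, and no p was computed for these 4 values.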
